A study of Homo sapiens with 6 samples.

How the data were processed

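The series holds 6 poly(A) RNA sequencing libraries of MCF-7 cells, 3 transfected with a non-targeting siRNA pool (siCtrl) and 3 with a pool against SRA (siSRA), at 25 nM for 32 h per the labels. Per the submitters' processing notes, reads were aligned to hg19 with TopHat and Bowtie and the groups compared with Cuffdiff, with versions, settings and annotation not stated. The labels' protocols state that cDNA was fragmented with DNase I. There were 2 deposited tables, made without and with assembly of new genes.

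Per the file headers, each table gives FPKM (fragments scaled to transcript length and to the number of mapped fragments) as 1 value per gene and group. The log2 fold change the authors deposited is that of siSRA over siCtrl. The deposited test statistic, p-value and q-value are those of Cuffdiff. The tables have 0 columns of values per replicate. It was checked on the tables that the deposited log2 ratio is the log2 of the ratio of both FPKM values, that the deposited p is the two-sided normal p of the test statistic (largest gap 2.66e-06 in the authors' deposited table), and that the deposited q is the Benjamini-Hochberg adjustment over tested genes (largest gap 1.18e-05 in the authors' deposited table). In each table, 4 lines without a gene were left out. Fold change and z-score columns added in a spreadsheet were not used. Of 24000 genes in the table without assembly, 14695 were tested, 9272 were not tested by Cuffdiff, 30 failed and 3 had too many fragments. The table with assembly had 31070 loci, of which 21479 were tested and 6915 had no gene name. In the first table, 168 tested genes were listed at 0 in a group and have no finite ratio, and 392 rows join several genes. FPKM values summed to 498975 in siCtrl and 502928 in siSRA. No read totals are in the files, so no counting interval could be computed.

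The table without assembly was the main one. A gene was called when it was tested and its q was under 0.05. The standard error implied by the deposited statistic is the absolute log2 ratio divided by the absolute test statistic, and 95% intervals are normal intervals from it. No test of this comparison was refitted. The choices of table, threshold, gene lists, named genes and alternatives, with the exceptions given below, were made before the data were examined. The genes named were SRA1, then the 12 largest log2 falls and the 12 largest rises among called rows with a single gene symbol and an FPKM of at least 1 in the higher group (only 4 rises met this), up to 4 called members of each gene list, ESR1, PGR, TFF1, GREB1 and the genes next to SRA1, and the 2 largest falls and rises among unannotated loci by the same FPKM rule. Genes named outside this rule are said to be so, or are members of a list that had an unadjusted p under 0.05 or were called when adjusted over the list alone, which were named after their values were seen.

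There were 23 gene lists, and 638 of their 642 members were found in the main table by symbol. For each list the median log2 ratio of members tested at a mean FPKM of at least 1 (12262 genes with a ratio as background) was set against 10000 random lists of the same size drawn from the same of 20 bins of mean FPKM. Fisher's exact test, two-sided, compared called members with the other background genes, with Benjamini-Hochberg adjustment over the lists. The adjustment over the list alone used the deposited p-values of its tested members. Some genes are in more than 1 list.

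Transcript sequences, GC content, length and 3′ UTRs came from GENCODE v29 (GRCh38), matched to the tables by gene symbol and older symbols, with 1 coding transcript per gene. Of 12000 single-gene rows tested at an FPKM of at least 1, 10834 (90.3%) were matched, including all 73 called lower. No coordinate was converted between builds. The GC and length trend was a smooth fit to the log2 ratios, which were clipped before fitting. For the 7-base sites, 10595 genes with a 3′ UTR of at least 50 bases were searched. Each site's association with the log2 ratio was computed among uncalled genes, and sites were then counted in called genes against 10000 random sets of uncalled genes matched on 3′ UTR length. The same was done for the 4 sites of the SRA1 transcript most associated with a fall that do not overlap in it. Sites that lie apart in the transcript can still share bases, as GTCAATA and TCAATAA do. SRA1 was left out of these counts. The search was repeated with 100 shuffled SRA1 sequences, and with each of 419 rearrangements of the leading site. Exact runs shared with the SRA1 transcript were compared with length-matched random sets.

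The list step was tested on simulated data for the 12262 genes, with noise independent between genes. In it, 10 of 10 lists of 30 genes shifted by 0.15 fell outside the central 95%, as did 6 of 200 unshifted lists. Fisher's test had a p under 0.05 in 10 of 10 lists with called genes planted, a count fixed by the planting, and in 5 of 200 others. In simulated data on the 10595 genes, the site search recovered 36 of 40 planted sites, and its permutation p was under 0.05 in 10 of 10 simulations with planted sites and in 0 of 10 without. The search for shared runs found the planted length in 100 of 100 random sequences.

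Alternatives were q thresholds of 0.01 and 0.1, a mean FPKM of at least 1 or 5, Benjamini-Hochberg adjustment recomputed, a minimum absolute log2 ratio of 1, the table with assembly, centring on the median, and pseudocounts of 1 and 0.1. Leaving out genes with the GTCAATA site or with any of the 4 leading SRA1 sites, and removing the GC and length trend from the lists, were added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.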

Results

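Messenger RNA was measured by poly(A) RNA sequencing in MCF-7, an established human breast cancer cell line that expresses the estrogen receptor. Cells were transfected with a pool of siRNAs against SRA, the steroid receptor RNA activator encoded by SRA1, or with a non-targeting pool. Each pool was used at 25 nM and RNA was collected after 32 h. There were 6 libraries, 3 with the non-targeting pool (siCtrl) and 3 with the SRA pool (siSRA), which the labels call biological replicates. The authors' deposited tables hold 1 FPKM value per gene and group, so no value per replicate could be given, and the number of reads behind each library is not given by these files. The spread between replicates enters here only through the authors' Cuffdiff test, as the standard error of the log2 ratio of siSRA to siCtrl implied by the deposited test statistic. The settings of that test are not stated, so this error and the intervals from it are not a measured replicate spread of each gene. At an FPKM of 5 to 20 in the mean of both groups, the median implied standard error was 0.115, and a log2 ratio of 0.42 would have been called at that error. Below an FPKM of 1 the median implied standard error was 0.345 and the corresponding ratio 1.26.

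SRA1 gives rise both to noncoding RNAs that act as coactivators of steroid receptors and to transcripts that encode a protein, SRAP. The level of SRA1 was read first, as a check that the siSRA group carried the knockdown. The SRA1 row, at 139929651 to 139937678 on chromosome 5 (hg19), fell from 18.8 FPKM in siCtrl to 1.61 FPKM in siSRA, 11.7-fold lower. The log2 ratio was −3.55 with an implied standard error of 0.233, a 95% interval from −4.01 to −3.09, and both p and q are listed as 0 in the authors' deposited table. A gene-level value of poly(A) RNA does not separate the noncoding from the coding transcripts. The adjacent genes were not called. The log2 ratio was −0.02 (−0.31 to 0.28) for the row that joins ANKHD1, ANKHD1-EIF4EBP3 and EIF4EBP3, −0.11 (−0.48 to 0.27) for APBB3 and 0.05 (−0.14 to 0.23) for SLC35A4.

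The series asks which genes depend on SRA RNA in these cells. Most of the changes were decreases. RACGAP1, a regulator of Rho GTPases needed for cytokinesis, and KIF14, a mitotic kinesin, were among the largest falls, together with NMD3, an export adaptor of the large ribosomal subunit, and PAICS, an enzyme of purine synthesis. The largest called rise at an FPKM of at least 1 was in RMRP, the RNA component of the ribonuclease MRP. Of 24000 genes in the table made without assembly of new genes, 14695 were tested, and 82 had a q under 0.05 in the authors' deposited table. Of these, 76 were lower and 6 higher in siSRA, so that 92.7% were lower. The median log2 ratio of tested genes at a mean FPKM of at least 1 was −0.0028, and 5% and 95% of them lay below −0.21 and 0.17. An unadjusted p under 0.05 was listed for 408 genes (2.78%) in the authors' deposited table, 312 of them lower and 96 higher.

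After SRA1, the largest fall was in MSRB2, a mitochondrial methionine sulfoxide reductase, from 17.6 to 2.70 FPKM (log2 ratio −2.71, implied standard error 0.130). Its level depended on the locus used: with assembly the locus has another start, and MSRB2 fell from 128 to 15.9 FPKM (−3.02, 0.382). RACGAP1 fell from 55.6 to 21.9 FPKM (−1.35, 0.0955). NMD3 fell from 137 to 67.2 FPKM (−1.03), KIF14 from 9.66 to 4.92 (−0.97) and PAICS from 101 to 51.6 (−0.96). UGT8, a galactosyltransferase of sphingolipid synthesis, fell from 6.52 to 3.13 FPKM (−1.06). A note in the authors' deposited table says that many mismatches were seen for UGT8 in a genome browser and that it was set aside as a candidate. The other named falls had log2 ratios of −1.04 (C3orf58, 3.15 to 1.53 FPKM), −0.96 (LINGO1, 6.74 to 3.46 FPKM), −0.86 (DUSP2, a MAP kinase phosphatase, 2.64 to 1.46 FPKM), −0.82 (CTDSPL2, 8.18 to 4.62 FPKM) and −0.82 (EFEMP1, a matrix glycoprotein, 6.71 to 3.80 FPKM). The largest q among the 12 named falls was 0.000618, for DUSP2, in the authors' deposited table.

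RMRP rose from 10.6 to 26.02 FPKM, a log2 ratio of 1.30 with an implied standard error of 0.280 and a q of 0.00124 in the authors' deposited table. RMRP has no poly(A) tail, so poly(A) libraries hold it only in part. IFI6, an interferon-stimulated gene, rose from 18.1 to 28.5 FPKM (0.66, with a q of 0.00104 in the authors' deposited table). HMOX1, which encodes heme oxygenase, rose from 7.18 to 10.2 FPKM (0.50, with a q of 0.00705 in the authors' deposited table). PSKH1, a serine kinase, rose from 9.97 to 13.6 FPKM (0.44, with a q of 0.00419 in the authors' deposited table). The other 2 rises lay under an FPKM of 1 and were named after their values were seen: NRSN1 (2.35, 0.195 to 0.996 FPKM) and C14orf23 (3.96, 0.0206 to 0.321 FPKM).

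**Figure D1:**
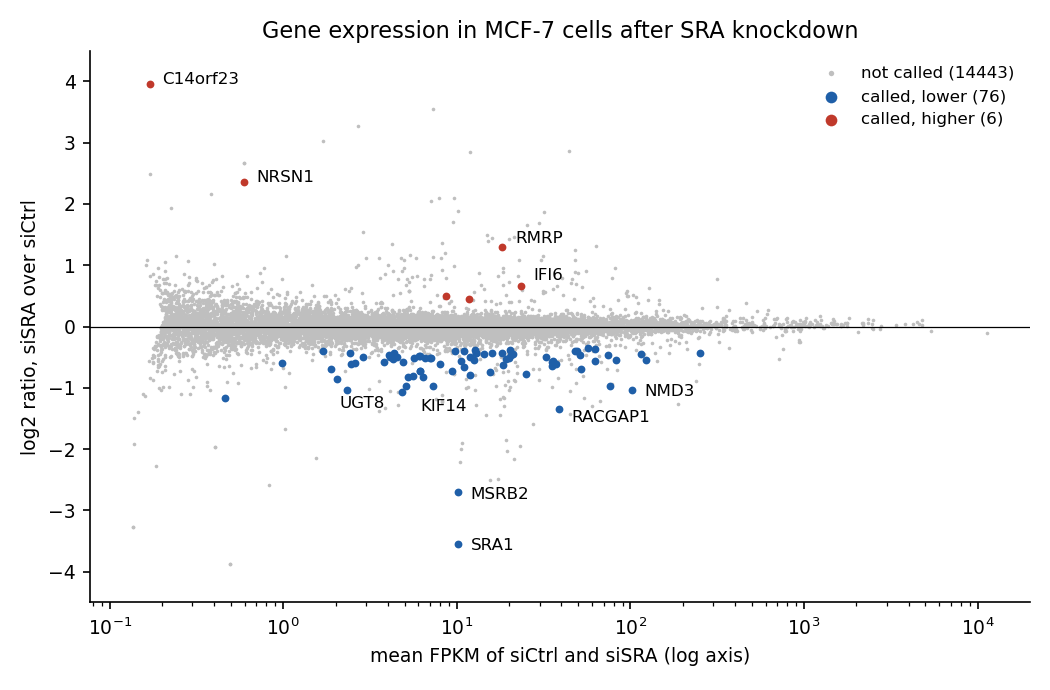
Log2 ratio of siSRA to siCtrl against the mean FPKM of both groups (log axis) for tested genes, 1 point per gene, with called genes coloured by direction. Most of the 76 genes called lower, among them SRA1, MSRB2 and RACGAP1, lie at a mean FPKM of 1 to 100, and 6 genes were called higher; 2 uncalled genes beyond the axis are not drawn.

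The sequences of the siRNAs are not given in the sources used here, so the 3′ UTRs of the changed genes were compared with the SRA1 transcript itself, as transcribed in GENCODE v29 (GRCh38). Among 10520 genes that were not called, the 7-base site most associated with a fall, of 16131 sites found in at least 50 of them, was GTCAATA. That site occurs once in the SRA1 transcript, at base 1223 of 2107, in coding exon 4 of 5 (GRCh38, chromosome 5, 140551095 to 140551101, minus strand). It was then counted in the called genes, which had not been used to choose it. Of 72 called lower genes with a 3′ UTR of at least 50 bases, 53 (73.6%) had the site, against 640 of the 10520 uncalled genes (6.08%). Uncalled genes matched on 3′ UTR length gave 6.52 such genes on average and at most 16 in 10000 random sets (permutation p 0.0001, one-sided, the smallest that the permutations can give). None of the 3 called higher genes searched had it. Of 419 rearrangements of the same 7 bases, the most frequent was found in 35 called lower genes and the median in 12, and the most frequent of them shares 6 bases with GTCAATA by overlap. RACGAP1, C3orf58, KIF14, PAICS, LINGO1, DUSP2 and EFEMP1 had the site, 7 of the 11 named falls besides SRA1. MSRB2, UGT8, NMD3 and CTDSPL2 did not. GTCAATA was chosen by its association among the uncalled genes, so values of uncalled genes with a 3′ UTR site restate that choice and are not separate support. Of uncalled genes with the site, 81.9% had a log2 ratio below 0, against 49.9% of those without it. Against uncalled genes of like GC content without the site, their median difference in log2 ratio was −0.061. The association was not limited to 3′ UTRs: 401 uncalled genes with the site only elsewhere in the transcript had a median log2 ratio of −0.065. Against uncalled genes of like GC content with no site in the transcript, the median difference was −0.039 for these genes and −0.065 for genes with a 3′ UTR site. Of the 19 called lower genes without GTCAATA in the 3′ UTR, 10 (UGT8 and CTDSPL2 among them) had another of the 4 leading SRA1 sites, where length-matched genes gave 8.14 on average (95% of random sets 4 to 12), and 9 (MSRB2 and NMD3 among them) had none. GTCAATA lay elsewhere in the transcript in 3 of the 19 (SENP2, SKP2 and SRPR, named after their values were seen).

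**Figure D2:**
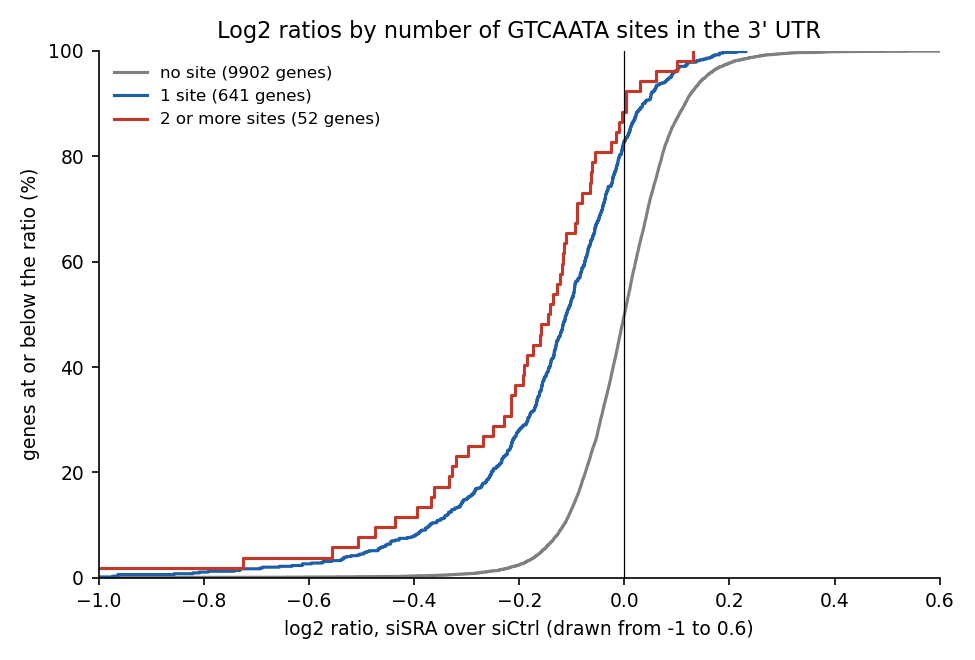
Cumulative share of genes (vertical axis) by log2 ratio of siSRA to siCtrl (horizontal axis, drawn from −1 to 0.6), for genes with 0, 1 or several GTCAATA sites in the 3′ UTR. The curve of 9902 genes with no site centres near 0, that of 641 genes with 1 site lies to its left with a median of −0.11, and that of 52 genes with 2 or more sites has a median of −0.14. Most of the genes drawn are the uncalled genes among which the site was chosen.

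SRA was first described as a coactivator of steroid receptors, so estrogen receptor signalling was the first gene list examined. The receptor itself and its best known target genes were not called. ESR1 had 51.5 FPKM in siCtrl and 54.6 in siSRA, a log2 ratio of 0.08 with a 95% interval from −0.13 to 0.30. The log2 ratio was 0.13 (−0.10 to 0.36) for PGR at 1.07 FPKM in siCtrl, 0.05 (−0.24 to 0.34) for TFF1 at 4151 FPKM and 0.06 (−0.26 to 0.37) for GREB1 at 71.7 FPKM. Of 49 tested estrogen receptor targets, 0 were called by the authors' Cuffdiff test and 0 when adjusted over the list alone, and 3 had an unadjusted p under 0.05, all higher (HSPB8, PTGES and EGR3). As a set they lay slightly high. Their median log2 ratio was 0.072 over the 47 at an FPKM of at least 1, with 37 above 0 and 10 below, and the central 95% of 10000 random lists matched on FPKM ran from −0.030 to 0.030. Among 35 nuclear receptors and SRA-binding coregulators, 0 were called by the authors' Cuffdiff test over all genes and 1 when adjusted over the list alone, the glucocorticoid receptor gene NR3C1 (log2 ratio −0.39, with the GTCAATA site). That list had a median of −0.020, inside its random range, and 1 member with an unadjusted p under 0.05.

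A further 21 gene lists were examined in the same way, and 9 of the 23 lists had a median outside the central 95% of matched random lists. The number expected by chance, 1.15, holds only for genes that vary independently. Genes of a list can vary together, which makes the random ranges too narrow, so 9 against 1.15 does not measure chance. Genes are not replicates, so these percentiles describe the libraries, and the p-values given here rest on the authors' test. The interferon-stimulated genes lay high, with a median of 0.146 (random range −0.056 to 0.047), 16 above 0 and 6 below. The size of that shift depended on weakly expressed members, and the median was 0.086 at a mean FPKM of at least 5 (12 genes), still above the random range. IFI6 was called there over all genes and also when adjusted over the list alone. ISG15, IFIT1, IRF9 and OAS1 were higher and OAS3 lower at an unadjusted p under 0.05 in the authors' deposited table. The cell cycle and DNA replication genes lay lowest, with a median of −0.104 (random range −0.033 to 0.028), 38 below 0 and 4 above. AURKA, the Aurora A kinase gene, fell from 97.3 to 66.9 FPKM (−0.54, with a q of 0.00164 in the authors' deposited table), and CENPF (−0.29) was the second member called when adjusted over the list alone. Neither AURKA nor IFI6 had the GTCAATA site in the 3′ UTR, but AURKA had another of the 4 leading SRA1 sites. At least 1 of these 4 sites was found in 31.5% of uncalled genes. The immediate early and growth factor genes (median 0.094), the replication-dependent histone genes (0.109), the mesenchymal, matrix and migration genes (0.053) and the markers of other cell types (0.133, over 4 genes at an FPKM of at least 1) also lay above their random ranges. The subunits of CTCF, cohesin, Polycomb and Trithorax complexes (−0.076) and the Notch pathway genes (−0.069) lay below theirs.

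**Figure D3:**
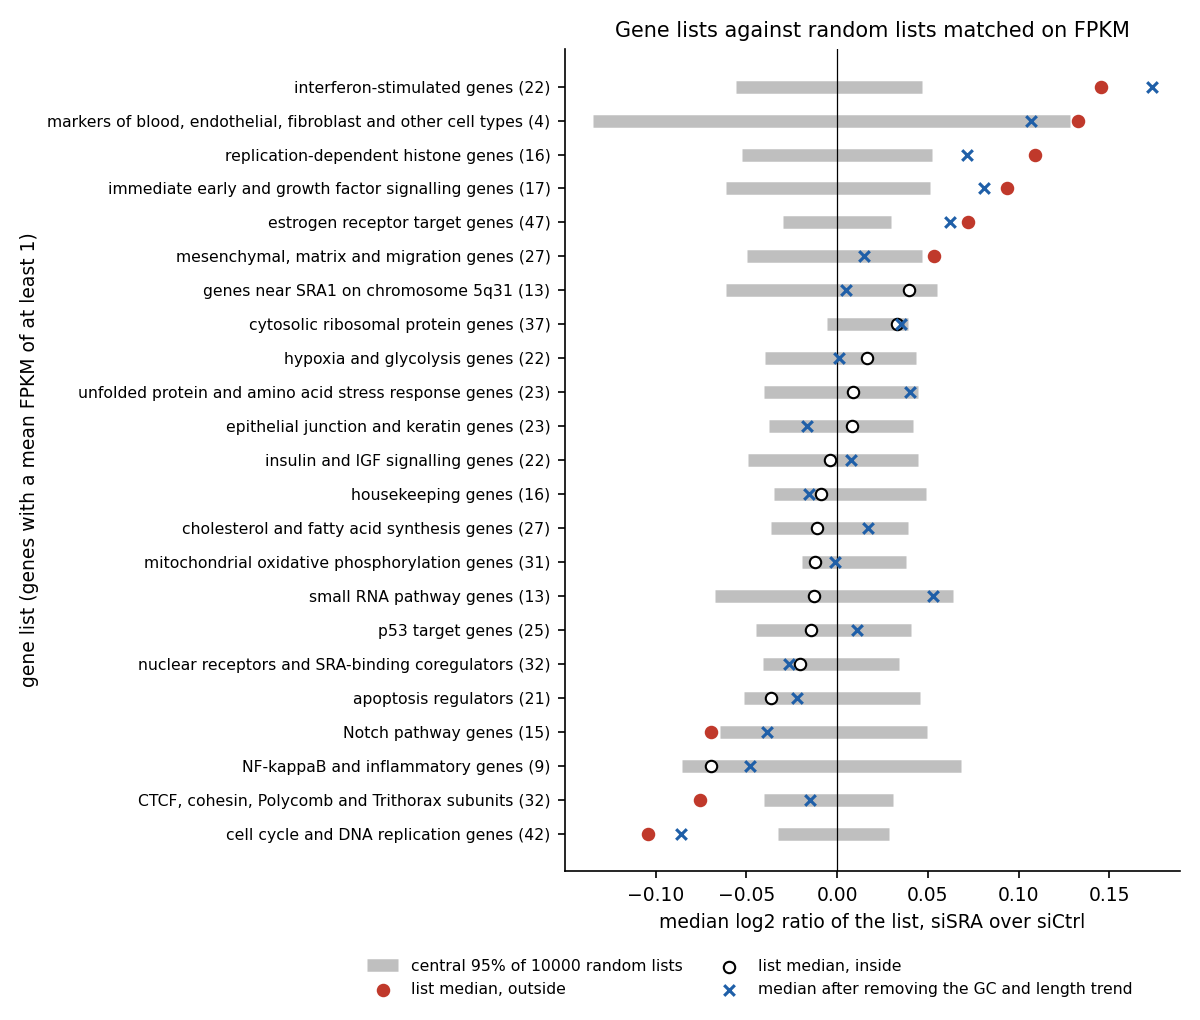
Median log2 ratio of siSRA to siCtrl for each of 23 fixed gene lists (points), with the central 95% of 10000 random lists matched on FPKM (bars). The interferon-stimulated genes have the highest median, 0.146, and the cell cycle genes the lowest, −0.104.

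Called genes were few in every list. TGFBR1, a receptor of transforming growth factor beta, fell from 5.84 to 3.93 FPKM (−0.57) in the mesenchymal list, and UQCRC2, a complex III subunit, fell from 133 to 97.9 FPKM (−0.45) in the oxidative phosphorylation list. UQCRC2 has the GTCAATA site and was not called in the table with assembled new genes. Its log2 ratio there was also −0.45, with an implied standard error of 0.128 against 0.0941 without assembly. Each was also the only member called when adjusted over the list alone. Adjustment over the list alone also called MCL1 (−0.38) among the apoptosis regulators and PKM2 (−0.53) among the hypoxia and glycolysis genes, both with the GTCAATA site and neither called over all genes. In the other lists examined, 0 members were called by the authors' Cuffdiff test over all genes or when adjusted over the list alone. At an unadjusted p under 0.05 in the authors' deposited table, those lists held 4 immediate early genes, 1 histone gene and 1 p53 target, all higher, 1 lower insulin and IGF signalling gene, and 0 members of the rest. No list passed Fisher's exact test for called members, with a smallest two-sided p of 0.131 before and 1 after adjustment over the lists. Called genes were rare in the background, so few were expected in lists of this size and that test could show little. The medians inside their random ranges were −0.015 for p53 targets, −0.036 for apoptosis regulators, 0.0081 for epithelial genes, 0.0090 for unfolded protein response genes, 0.016 for hypoxia and glycolysis genes and −0.011 for cholesterol and fatty acid synthesis genes. They were −0.0040 for insulin and IGF signalling genes, −0.070 for NF-kappaB genes, −0.013 for small RNA pathway genes, −0.012 for oxidative phosphorylation genes, 0.033 for ribosomal protein genes, −0.0087 for housekeeping genes and 0.040 for genes near SRA1, with SRA1 itself left out.

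The log2 ratios also followed base composition. Across 10834 genes, which are not independent replicates, Spearman's rho was 0.50 between the log2 ratio and the GC content of the transcript, and −0.193 between the log2 ratio and transcript length. The median log2 ratio rose from −0.069 in the fifth of genes with the lowest GC content to 0.057 in the fifth with the highest. After a smooth trend on GC content and length was removed, the medians of 5 lists stayed outside their random ranges in the same direction: estrogen receptor targets (0.062), interferon-stimulated genes (0.173), cell cycle genes (−0.086), immediate early genes (0.081) and histone genes (0.072). The mesenchymal list (0.015), the CTCF, cohesin, Polycomb and Trithorax list (−0.015), the Notch list (−0.039) and the markers of other cell types (0.107) came to lie inside.

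The second deposited table adds loci assembled from the reads, some of which have no gene name, and was used to ask whether unannotated transcripts changed. Few of them were called. The median of tested loci without a gene name was 0.598 FPKM in siCtrl. For annotated genes under an FPKM of 1, only log2 ratios beyond about 1.26 would be called at the median implied error. Loci that were not called may therefore have changed. Of 6864 tested loci without a gene name, 6 were called in the authors' deposited table, 4 lower and 2 higher, and 40 had an unadjusted p under 0.05. The largest falls were at 24762785 to 24762853 on chromosome 21, from 901 to 78.0 FPKM (−3.53, implied standard error 0.853), and at 31961316 to 31961477 on chromosome 1, from 117 to 13.03 FPKM (−3.16, 0.508). The rise that met the FPKM rule was at 136292262 to 136292359 on chromosome 4, from 1189 to 1871 FPKM (0.65). All positions are in hg19. These 3 loci are 69, 162 and 98 bp long, shorter than the median of 768 bp, so that their FPKM rests on a very short length. The other 3 were named after their values were seen: falls at 22549927 to 22550552 on chromosome 7 (−2.06) and at 119474366 to 119474822 on chromosome 11 (−1.23), and a rise at 85537609 to 85547973 on chromosome 16 (0.73), under an FPKM of 1. Among loci with a gene name, 59 were called in this table, 57 of which were called in the table without assembly, all in the same direction. Of the 82 genes called without assembly, 25 were not called with it.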

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

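The looks at the 10 best measured small RNAs and at the histone genes were chosen only after the result was seen. MIR3648 and MIR3687 are microRNA genes annotated within ribosomal DNA sequence on chromosome 21. In the table with assembled new genes, which the gene comparisons did not use as their source, their joint locus at 9825436 to 9827714 on chromosome 21 (hg19) rose from 173 to 358 FPKM, a log2 ratio of 1.05 with a q of 5.33e-05 in the authors' deposited table. It drew attention because it was called there while the table without assembly gave 66.2 FPKM in siCtrl and 58.4 in siSRA, a log2 ratio of −0.18 with a p of 0.479 in the authors' deposited table.

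RMRP (log2 ratio 1.30 and, with assembly, 1.28) and the MIR3648,MIR3687 locus are both RNAs that poly(A) selection should largely remove, so more carry-over of RNA without poly(A) tails in the siSRA libraries could explain both rises. Across 241 other small RNAs of that kind the median log2 ratio was −0.0067 (bootstrap interval −0.073 to 0.090, SD of the ratios 0.70), so they did not rise as a set. Most of them are small nucleolar RNAs, some entries repeat, and their implied standard errors were large (median 3.62). They may not stand for RMRP, so no conclusion on carry-over was drawn from them. The 10 small RNAs with an implied standard error under 0.5 had a median of 0.12, with 8 above 0 and a range from −0.27 to 0.41, below RMRP. The highest was RPPH1, with a p of 0.0406 in the authors' deposited table, so carry-over is not excluded. Replication-dependent histone mRNAs, most of which lack poly(A) tails, lay high by far less (median 0.109). Carry-over of ribosomal RNA at the MIR3648,MIR3687 locus was not tested, because RN45S has no tested value, and a difference in how the tables count that locus and a real rise after loss of SRA stay open.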

How the results depend on the processing

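Leaving out genes with the GTCAATA site or with any of 4 SRA1 sites, and removing the GC and length trend were chosen only after the data were seen. The 82 called genes became 10 (7 lower, 3 higher; 70% lower) with an absolute log2 ratio of at least 1, which drops smaller changes by construction, and 29 (23 lower, 6 higher; 79.3% lower) without genes with the site. They became 19 (13 lower, 6 higher; 68.4% lower) without genes with any of the 4 sites, against 92.7% lower in all. Both counts keep 4 lower genes that were not searched, SRA1 among them, so 19 and 9 searched lower genes lacked the site and all 4 sites in the 3′ UTR. Of uncalled genes, 31.5% had at least 1 of the 4 sites, so part of the second drop follows from how common these sites are. The other settings gave 59 to 94 called genes, 88.1% to 95% of them lower. Of the 6 unannotated loci, 2 passed a q under 0.01. SRA1 kept its fall, at −3.55 with assembly, −3.55 centred and −2.93 with a pseudocount of 1. Between 7 and 9 lists lay outside their random ranges under each alternative, and the estrogen receptor, interferon and cell cycle lists stayed outside without genes with the site (0.070, 0.164 and −0.104) and without genes with any of the 4 sites (0.064, 0.244 and −0.104). The mesenchymal list (0.054) and the markers of other cell types (0.127, 3 genes) came inside without genes with any of the 4 sites. The interferon median stayed above its random range under every alternative but varied, with 0.086 at a mean FPKM of at least 5, 0.092 with a pseudocount of 1, 0.095 with no filter, 0.119 with assembly and 0.244 without genes with any of the 4 sites, and under the first 4 of these another list lay higher. The NF-kappaB list reversed, from −0.070 inside its range to 0.085 above it, at a mean FPKM of at least 5, which leaves 5 genes. The mesenchymal list came inside at that filter (0.031), the Notch list with assembly (−0.075) and the markers of other cell types with assembly (0.127), with no filter (0.127) or without genes with the site (0.133); the cause was not tested. Removing the trend on GC content and length brought 4 lists inside and put 2 outside, the unfolded protein response (0.040) and ribosomal protein genes (0.035). Of the 19 named called genes, 18 were called with assembly, UQCRC2 being the exception, with a log2 ratio of −0.45 both without and with assembly. No paired analysis was possible because the tables hold 1 value per group, and for the same reason leaving out each replicate, the replicate block and other splits of the samples were not run. Depth is not given, and below an FPKM of 1 only ratios beyond about 1.26 would be called at the median implied error.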

Other observations

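The tests of overall scaling, of the single site GTCAATA, of the run shared by CRIP2, of other sites in genes without GTCAATA and of lists without genes with these sites were chosen only after the results they concern had been seen. Loss of SRA could lower gene expression through its coactivator role, which could give mostly falls, as seen here (76 of 82 called genes). The estrogen receptor targets did not follow that direction, since their median lay above 0. ESR1 itself was not called. No hormone conditions were compared, so these values do not test the coactivator role. The set of falls cannot be assigned to SRA from these data alone, because 1 siRNA pool was used without a rescue and without values for single siRNAs.

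A candidate explanation for many of the falls is an off-target effect, in which the seed of an siRNA in the pool pairs with 3′ UTRs as a microRNA does. The data argue against some others. All genes at an FPKM of at least 1 had a median log2 ratio of −0.0028 (SD 0.215). The called lower genes had −0.54, so no scaling shift of all genes gave the falls. The fitted GC and length trend had an SD of 0.0495, small against falls of that size. After its removal the median of the called lower genes was −0.49 (bootstrap interval −0.55 to −0.46). These genes were chosen for low ratios, so that median is not a test of the trend. SRA1 holds 0.118% of the copies of the site in siCtrl cells, counting its own and those in 3′ UTRs. That share argues against release of a microRNA held by SRA1, but no microRNA was identified or measured. The median longest run shared with SRA1 was 12 bases, with 11 to 12 in random sets. The mean was 12, against 11.8 in random sets with an upper end of 12.01. No clear excess of long shared runs was thus seen in the set, and cleavage of a few genes is not excluded. Only CRIP2, 1 of 72 genes, passed the bound for such runs set in advance, with 16 bases (0.462% of all genes have a run this long), a reading of that bound adopted after the value was seen. Seed pairing has values it needs: the 4 leading SRA1 sites were 2.00 times as frequent in called lower genes as in length-matched genes. Shuffled SRA1 sequences gave a ratio as high in 1 of 100. A site as strongly associated as GTCAATA was found in 3 of 100. No other site was that strongly associated, so those 3 sequences held GTCAATA itself. That count shows only how often shuffling gives this site and is not a test of its association. GTCAATA alone was 8.13 times as frequent in called lower genes as in length-matched genes, although genes with GTCAATA only outside the 3′ UTR also lay low. Open remain loss of SRA itself, the 19 called lower genes without GTCAATA in the 3′ UTR (3 have it elsewhere in the transcript), in which the other 3 sites were about as frequent as in length-matched genes, and CRIP2, which also has GTCAATA, so that cleavage and seed pairing cannot be told apart for it.

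The interferon-stimulated list lay high and the cell cycle list low, which could reflect a response that differs between the siRNA pools. The trend on GC content and length is argued against as the whole cause: after its removal the medians lay at percentiles 100 and 0 of matched random lists. Leaving out genes with any of the 4 SRA1 sites left both outside their random ranges (0.244 over 16 genes and −0.104 over 31). Direct pairing at these 4 sites in 3′ UTRs is therefore not the whole cause of the low cell cycle list. Such pairing would lower its targets, so for the interferon list, which lay high, leaving them out could not decide anything. Other sites and indirect effects were not tested. No test of growth was run. A difference in confluence or transfection between the groups and an effect of SRA stay open, since no value per replicate and no growth measurement is given.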
